A study of Homo sapiens with 2 samples.

How the data were processed

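Limbal basal epithelial cells of 2 donors were profiled by droplet single-cell RNA sequencing. Per the labels' protocols, superficial layers were scraped from the limbus and the remaining tissue was kept in dispase II at 10 mg/ml and 4 °C for 16 h. The loosened sheet was digested in 0.05% trypsin with 1 mM EDTA at 37 °C for 10 min. Cells at 1000 per µl entered a 10x Genomics Chromium controller, libraries were made with the 3′ kit of version 2, and sequencing ran on an Illumina instrument. The submitters' processing notes name CASAVA, Cell Ranger 2.1, Seurat 3.0 and the genome build hg19, with no role or order, and the series text mentions filtering and integration. Whether those steps shaped the deposited table is not given in the sources used here.

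The deposited values are whole-number UMI counts per gene and cell barcode, neither normalized nor scaled, with 0 values that were not whole and 0 below 0. The table held 32738 gene identifiers and 17587 barcodes in a single matrix. Barcodes end in the suffix 1 or 2, all barcodes of suffix 1 stand before those of suffix 2, and 103 barcode sequences occur with both. The suffixes were taken as the 2 libraries and the libraries as the replicates. No column name ties a library to a sample title, so libraries 1 and 2 here are suffixes, not the titles' numbers. P-values of the gene tests measure how far the difference between classes varied between these 2 libraries, with the spread moderated across genes. Each donor had 1 library. Gene symbols came from a table of gene identifiers, which named 23668 of them, and then from a GENCODE annotation, which brought the number to 31112. The 1626 without a symbol held 0.329% of UMIs, and older symbols in the gene lists were matched through RefSeq synonyms. These references are of GRCh38 and not hg19, so they gave names and the Y-linked genes to leave out, and no positions are given. XIST and Y-linked genes, 107 in all, were left out of reported results.

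Cells needed at least 500 genes and under 10% mitochondrial UMIs, which removed 35 cells for mitochondrial share and 0 for genes. Scrublet (scanpy 1.11.5), planned for doublets, called 2 of the 17587 cells and was taken as not working. In its place cells were scored by the share of simulated doublets among their neighbours, with 2 simulated per cell, and the top 5% of each library was removed, 355 and 525 cells. That left 16672 cells. Each UMI was assigned at random, with a chance of 50%, to the first or the second of 2 portions (seed 1). The first portion served to cluster and name cells and the other to test them. Clusters came from the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0, on 30 principal components of 2000 variable genes scaled within each library, with 20 neighbours. This gave 24 clusters.

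Markers of 14 classes, 19 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The scoring rule that names a cluster was set after cluster markers were seen and before any gene test. It needed a mean log2 fold of the markers, over a background matched by library with 5 CPM added, of at least 0.3. It also needed at least 3 markers of at least 5 CPM that were higher, at least 1 own marker among the 10 leading genes, and at least as many own markers there as of any other class. The last condition was added after the first form of the rule called the GPHA2 and FRZB cluster 18 fibroblast-like. Of the listed genes FCGBP, PECAM1, RGS5 and UHRF1 were not matched. Names are rebuilt from markers and are given as "-like".

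UMIs of the second portion were summed per library and class, and classes with at least 20 cells in each library were compared. The test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3, with TMM scaling, filterByExpr and the library as a block, two-sided, with Benjamini-Hochberg adjustment over the genes tested. The SE is the absolute log2 fold divided by the square root of the F statistic, and 1 residual degree of freedom remained before the spread was moderated across genes. Folds within a single library are differences of log2 CPM with a prior count of 2, which lie closer to 0 than the fitted folds where counts are low. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with an estimated correlation. The form with an estimated correlation rests on the 1 residual degree of freedom, so it could call almost no list here, whatever the correlation. Some estimates, which rest on the same degree of freedom, lay far above 0.01, so the preset form may overstate those calls. In the differentiated-like comparison they were 0.62 for ribosomal protein and 0.47 for tight and gap junction genes. Both lists stood at 1 in the proliferating-like comparison. Where every sum of a class was 0, the fold was set against 3 UMIs over both libraries, and with 1 to 3 UMIs an exact interval of the ratio is given. Such an interval pools the UMIs of both libraries and covers counting error only, not the spread between libraries. Shares carry exact binomial 95% intervals, computed with scipy 1.17.1. On simulated counts with 100 genes changed at each size and a dispersion of 0.05, the test recovered 16% of genes at a log2 fold of 1 and 88% at 2 for the differentiated-like comparison. It recovered 7% and 74% for the proliferating-like and 9% and 83% for the conjunctival-like comparison. The dispersion was set and not estimated from the data, and the simulated change was the same in both libraries. Far more genes were called in the data than were changed here, so these rates are not the power of the reported tests.

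The named genes of a comparison were the 12 highest and 12 lowest log2 folds among genes past the threshold, with at least 50 CPM in the higher class and the same direction in both libraries, without naming markers. TSPAN7, SOX17 and the 4 members with the smallest p of each list described were added. The results of some of these genes are not reported here. Which lists are described at length was chosen after the list results were seen. Cells of the epithelial classes and the unnamed clusters were ordered per library by diffusion pseudotime (30 neighbours, 10 components) from the progenitor-like class and split into 5 bins. Shares of cells with a UMI of a gene counted all UMIs of a cell, both portions included. For shares at equal depth cells were thinned to 3000 UMIs. The strand used in counting is not given in the sources used here, so antisense genes such as AQP5-AS1 are uncertain, as are close relatives such as the IFITM and SPRR genes. Summed counts of the libraries correlated over genes at 0.984 on the log2 scale, and their log2 folds over 12653 genes at 0.784, 0.647 and 0.683 for the differentiated-like, proliferating-like and conjunctival-like comparisons; genes are not independent replicates. The alternatives were DESeq2 1.42.0, RLE scaling, no count filter, no block, all classes in a single fit, resolutions 0.5 and 2.0, all UMIs for naming and testing, looser cell filters of 200 genes and 20% mitochondrial UMIs, doublets kept, genes scaled over both libraries, each library left out, and the position on the first principal component as the order. A naming limit of 0.5, libraries clustered separately, and naming without the leading gene condition were added after seeing the data.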

Results

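Single-cell RNA profiles were collected from basal epithelial cells of the human corneal limbus, the rim between cornea and conjunctiva where the stem cells of the corneal epithelium reside. The labels describe 2 samples of 1 group, from 2 donors, with no treated or control arm, so the comparisons the design allows lie between cell classes. The deposited table held 17587 cell barcodes in 2 libraries, against about 18000 cells stated by the study. Library 1 had 7096 barcodes and 98724703 UMIs, and library 2 had 10491 barcodes and 125088721 UMIs. UMIs per cell ranged from 3101 to 83614, with medians of 13474 and 11596 in libraries 1 and 2. The median cell showed 3257 and 2731 genes, and 3.46% and 3.22% of UMIs came from mitochondrial genes. After the cell filters 6721 and 9951 cells remained.

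The study set out to find the limbal stem cells and to order the cells along their differentiation. Limbal progenitor-like cells made up 13.5% ± 2.28 (SD, n = 2 libraries) of the cells kept, and corneal differentiated-like cells 17.7% ± 1.64. The differentiated-like share rested in library 2 on cluster 2, which scored 0.31 against the naming limit of 0.3: with a limit of 0.5 it was 13.8% in library 1 and 1.10% in library 2. With called doublets kept the share was 6.261% in library 1 and 14.15% in library 2. The progenitor-like class joined 2 clusters with GPHA2 and FRZB among their 10 leading genes, both known from the quiescent outer limbus, and 2 with CASP14 beside the interferon-induced IFITM1. The chemokine CXCL1 led cluster 7 of this class, and CXCL3 stood among the leading genes of cluster 9. KRT3, a keratin of the corneal epithelium, led each of the 3 differentiated-like clusters. Conjunctival-like cells, with KRT13, S100A8 and S100A9 among the leading genes of both clusters, took 6.19% ± 3.47, at 8.65% in library 1 and 3.74% in library 2, and 12.6% ± 1.23 at resolution 0.5. Proliferating-like cells, with UBE2C, BIRC5 and TOP2A among theirs, took 1.98% ± 0.194. Melanocyte-like cells with DCT, PMEL and TYRP1, the enzymes and matrix protein of pigment granules, took 1.58% ± 0.272. Vascular endothelial-like cells with ACKR1, CLDN5 and PLVAP were 57 of 6721 cells in library 1 (0.848%, exact 95% interval 0.643 to 1.10) and 7 of 9951 in library 2 (0.0703%, 0.0283 to 0.145), and with the libraries clustered separately they were 60 cells of library 1 and 0 of library 2. Fibroblast-like cells with KERA and LUM numbered 14 in library 1 and 8 in library 2, against 17 and 222 without the leading gene condition and 14 and 228 with the libraries clustered separately. Immune-like cells with C1QA and LYZ numbered 16. The other 58.3% ± 4.69 of cells lay in 10 clusters that met no naming rule. Intervals cover counting error only.

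No cluster carried the names superficial, goblet, lymphatic endothelial, pericyte or smooth muscle, Schwann or erythrocyte. Single cells of these types inside other or unnamed clusters were not counted. The conjunctival-like cluster 13 had 3 superficial markers, KRT4, LYPD2 and PSCA, among its 10 leading genes, against 4 conjunctival markers. KRT4 also stood among the leading genes of the conjunctival-like cluster 14, so superficial cells in this class are not excluded. Without a superficial class the planned comparison of superficial with differentiated cells was not made. The labels state that superficial layers were scraped off before digestion. Most clusters were filled by a single library. Clusters 9 and 19 held most progenitor-like cells of library 1 and clusters 7 and 18 most of those of library 2, while differentiated-like cells came mostly from cluster 8 in library 1 and cluster 2 in library 2. Conjunctival-like cells came mostly from cluster 13 in library 1 (573 of 581 cells) and cluster 14 in library 2 (333 of 372). Cluster 15 missed the naming limit as conjunctival with 0.28, at 4.81% of library 1 and 0.0603% of library 2. Cluster 11 scored 0.58 for the conjunctival markers with none among its 10 leading genes, at 0.134% and 7.92%. Those genes held MMP10, a progenitor naming marker, and HLA-DRA, an immune naming marker. MMP10, AC093496.1, IFITM2 and IFITM3 also stood among the leading genes of the progenitor-like cluster 19.

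**Figure D1:**
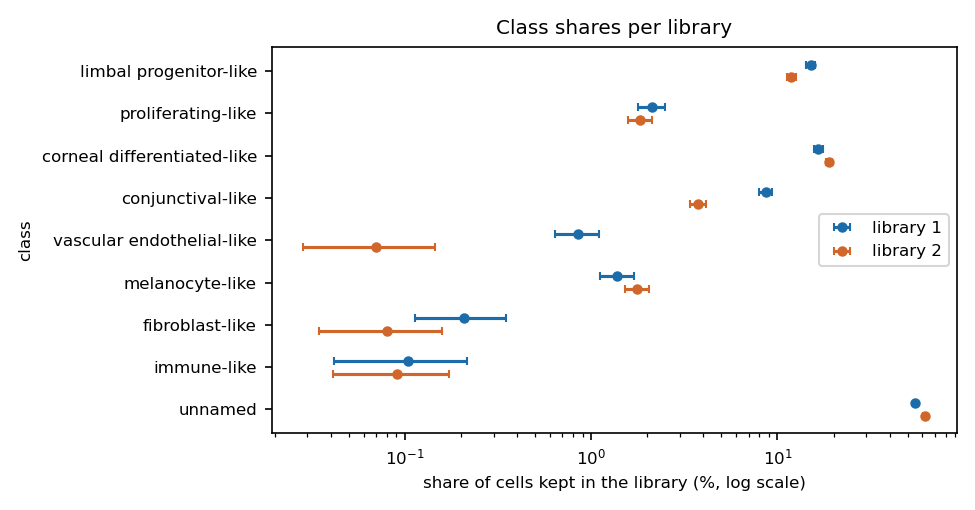
Share of the kept cells in each class, in percent on a log scale, for library 1 (6721 cells) and library 2 (9951 cells); bars are exact 95% binomial intervals and cover counting error only. The progenitor-like share was 15.1% and 11.9%, and the vascular endothelial-like share 0.848% and 0.0703%.

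Differentiated-like cells differed from progenitor-like cells in genes of tight and gap junctions, desmosomes and the cornified envelope, among others. MAL (ENSG00000172005), a membrane protein of apical transport, was higher by a log2 fold of 7.13 ± 0.42 (SE, n = 2 libraries). The uroplakin UPK1B was higher by 4.75 ± 0.34 and the matrix protein CRTAC1 by 4.27 ± 0.29. SCRG1 was lower by -7.69 ± 0.42 and the interferon-induced IFITM1 by -7.84 ± 0.39. The chemokine CXCL1 averaged 243.5 CPM in progenitor-like and 11.1 CPM in differentiated-like cells, a log2 fold of -4.48 ± 0.28.

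Of 12000 genes tested by edgeR's quasi-likelihood test, 1658 rose and 1527 fell in differentiated-like cells at a Benjamini-Hochberg adjusted p under 0.05, and 3178 of these 3185 moved the same way in both libraries. A gene with opposite folds in the 2 libraries could hardly pass this test, so that agreement is not separate evidence. Besides the genes above, PDE4C (6.45 ± 0.45), SPOCK1 (5.80 ± 0.45), LINC01474, FSIP1, SPRR1B, the cytokine IL36G, CLDN7 and the cytidine deaminase APOBEC3A were among the 12 highest. AC093496.1, SPARCL1, FAM107A, the complement protease gene C1R, MEG3, FXYD5, VIM and CXCL3 were among the 12 lowest. The adjusted p of the 24 ran from 1.24e-12 for IFITM1 to 6.88e-06 for VIM, which encodes the filament protein vimentin. Folds within a library were computed with a prior count of 2, which draws them toward 0 where counts are low, so the fitted fold can lie outside both. VIM differed between the libraries, at -5.82 in library 1 and -1.99 in library 2, and AC093496.1 stood at -8.09 and -4.35. Among the 24 genes, 12 were also among the 10 leading genes of a cluster of either class, MAL, CXCL1, SCRG1 and IFITM1 included, so clustering itself sets them apart.

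Of 14 tight and gap junction genes tested, 13 rose and 0 fell (13 adjusted over the list alone), with CLDN7 at 4.41 ± 0.30, OCLN, which encodes occludin, at 2.56 ± 0.33, and CLDN4 at 2.28 ± 0.30. The list stood above other genes by limma's camera test (adjusted p = 6.31e-08; adjusted p = 0.671 with an estimated correlation). Of 11 desmosome genes 9 rose and 1 fell (10 adjusted over the list alone), led by DSG1 (3.42 ± 0.30), DSC2 (2.53 ± 0.29) and DSP, the desmoplakin gene (1.63 ± 0.25). The camera adjusted p of the desmosome list was 0.00174, and the adjusted p = 0.671 with an estimated correlation. Of 13 cornified envelope genes, which make the tough protein shell of surface keratinocytes, 10 rose and 1 fell (12 adjusted over the list alone). SPRR1A stood at 5.97 ± 0.45, SPRR2A at 4.21 ± 0.33 and EVPL, the envoplakin gene, at 2.70 ± 0.28, with a camera adjusted p of 1.80e-05 (adjusted p = 0.671 with an estimated correlation). CLDN7, SPRR1A, SPRR2A and SPRR2D were among the 10 leading genes of the differentiated-like cluster 2. The junction and envelope lists are therefore not evidence independent of the clustering.

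Cholesterol synthesis genes rose in 8 of 14 cases and fell in 0 (9 adjusted over the list alone), with SQLE at 2.17 ± 0.31 and MVK at 1.98 ± 0.30. Their camera adjusted p was 0.00115 (adjusted p = 0.671 with an estimated correlation). Ribosomal protein genes fell in 11 of 20 cases and rose in 0 (16 adjusted over the list alone). RPL5 stood at -1.20 ± 0.27, RPS6 at -1.15 ± 0.28 and RPL3 at -1.12 ± 0.27, and the list's camera adjusted p was 1.80e-05 (adjusted p = 0.671 with an estimated correlation). The median cell held 7224 UMIs in the progenitor-like and 12870 in the differentiated-like class. Of 13 chromatin and growth genes 5 fell and 0 rose (5 adjusted over the list alone), among them STMN1 (-2.07 ± 0.27), PTMA (-1.19 ± 0.27) and NPM1 (-1.05 ± 0.26). The camera adjusted p for chromatin and growth was 0.0445, and the adjusted p = 0.671 with an estimated correlation.

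Of 10 stem cell candidate genes tested 6 fell and 0 rose (7 adjusted over the list alone), with VIM at -3.80 ± 0.54 and NGFR, a nerve growth factor receptor gene, at -2.05 ± 0.49. CDH2, the N-cadherin gene, had 3 UMIs in differentiated-like and 61 in progenitor-like cells, a ratio of 48.5 with an exact 95% interval of 15.8 to 242 for counting error only. The list holds TSPAN7 and SOX17, which the study chose on these cells, so it is not independent evidence, although neither passed the expression filter. Its camera adjusted p was 0.00500 (adjusted p = 0.671 with an estimated correlation). Notch and Wnt genes split. Of 8 Notch genes 3 rose and 3 fell (6 adjusted over the list alone), with the target HES4 at 2.75 ± 0.31 and the ligand DLL1 at -3.70 ± 0.40, and the list had a camera adjusted p of 0.747, a median log2 fold of 0.14 and a mean of -0.38. Of 11 Wnt genes 1 rose and 4 fell (5 adjusted over the list alone), with WNT4 at 1.93 ± 0.32 and WNT10A at -2.51 ± 0.31, and a camera adjusted p of 0.350. Of 12 inflammatory genes 5 rose and 4 fell (10 adjusted over the list alone). IL1RN, the natural blocker of interleukin 1, stood at 3.27 ± 0.28 and CXCL3 at -3.78 ± 0.35, with a camera adjusted p of 0.536. Of 18 antigen presentation and interferon genes 3 rose and 4 fell (9 adjusted over the list alone), with IFI27 at 3.63 ± 0.33 and IFITM3 at -3.71 ± 0.29, and a camera adjusted p of 0.376. DESeq2 called 3 of the stem cell candidates, 5 of the cholesterol synthesis and 3 of the Wnt genes. The IFITM and SPRR genes are close relatives, so the split of reads among members is uncertain. Without the library as a block 636 genes passed, all among the 3185 in the same direction, and DESeq2 called 1413, of which 1382 were; VIM lost its call in both fits and SPRR1B without the block. A stricter naming limit of 0.5, which left out cluster 2, gave 1913 genes.

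**Figure D2:**
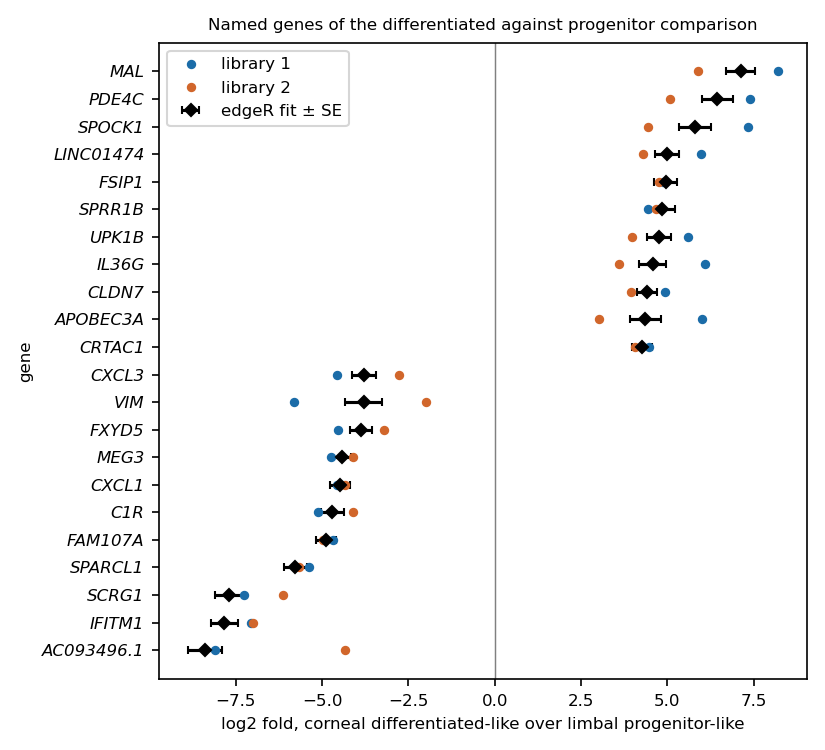
Log2 fold of 22 of the 24 named genes, corneal differentiated-like over limbal progenitor-like; diamonds are the edgeR fit with its SE, and dots are the fold within library 1 and library 2, computed with a prior count of 2 and so closer to 0 where counts are low. The rule that chose the genes asked for the same side of 0 in both libraries; MAL stood at 8.19 and 5.89.

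Proliferating-like cells were clustered and named by cell cycle genes such as MKI67 and TOP2A, so higher levels of mitosis and replication genes were set by how the class was drawn. TPX2, a spindle assembly factor, was higher than in progenitor-like cells by a log2 fold of 7.38 ± 0.39 (SE, n = 2 libraries), CDC20, an activator of the anaphase-promoting complex, by 6.96 ± 0.41, and ANLN, the contractile ring gene anillin, by 6.89 ± 0.43. CCNB2 (ENSG00000157456), a mitotic cyclin, had 249 UMIs against 0, at least 190-fold higher by a floor of 3 UMIs over both libraries. SCRG1 had 0 UMIs in proliferating-like and 452 in progenitor-like cells, at least 65.9-fold lower. SPARCL1 was lower by -3.50 ± 0.32, the chemokine CXCL8 by -3.26 ± 0.38 and ID4 by -2.84 ± 0.26.

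Of 10235 genes tested by edgeR, 754 rose and 503 fell at a Benjamini-Hochberg adjusted p under 0.05, and 1255 of the 1257 moved the same way in both libraries. Here too the shared direction follows largely from the test. PBK (449 UMIs against 3, ratio 342, exact 95% interval 116 to 1664 for counting error only), TROAP, KIF23, CDKN3, ZWINT, UBE2T, RACGAP1 and CENPM completed the 12 highest. AC093496.1, IFITM1, the taurine transporter SLC6A6, CXCL3, FAM107A, SERPINF1, SELENOM and IFITM3 completed the 12 lowest. The adjusted p of the 24 ran from 4.25e-10 for TPX2 to 2.10e-05 for SERPINF1. AC093496.1 stood at -6.01 in library 1 and -1.23 in library 2. Of the 24 genes, 10 were also among the leading genes of a cluster of either class, PBK, CDC20 and SCRG1 among them.

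All 19 mitosis genes tested rose (19 adjusted over the list alone), with a camera adjusted p of 1.83e-32 (adjusted p = 0.743 with an estimated correlation), which is not evidence independent of the naming. Of 20 DNA replication genes 17 rose and 0 fell (18 adjusted over the list alone), with the licensing factors CDC6 at 4.83 ± 0.65 and CDT1 at 3.57 ± 0.41, and the replication clamp gene PCNA at 1.95 ± 0.27. That list had a camera adjusted p of 4.85e-12 (adjusted p = 0.743 with an estimated correlation). Of 13 chromatin and growth genes 9 rose and 0 fell (10 adjusted over the list alone), with STMN1 at 3.39 ± 0.28, HMGB2 at 2.79 ± 0.29 and EZH2 at 1.95 ± 0.33. Their camera adjusted p was 3.48e-05 (adjusted p = 0.743 with an estimated correlation). Of 12 tight and gap junction genes 6 rose and 0 fell (8 adjusted over the list alone), with CLDN7 at 1.57 ± 0.25 and a camera adjusted p of 0.000316 (adjusted p = 0.743 with an estimated correlation). Of 11 desmosome genes 4 rose and 1 fell (9 adjusted over the list alone), DSG1 at 1.92 ± 0.26 and PKP2 at -0.73 ± 0.23, with a camera adjusted p of 0.0324 (adjusted p = 0.743 with an estimated correlation). Of 10 cornified envelope genes 4 rose and 0 fell (5 adjusted over the list alone), with CSTA at 1.34 ± 0.23 and a camera adjusted p of 0.0383 (adjusted p = 0.743 with an estimated correlation).

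Cholesterol synthesis genes rose in 3 of 14 cases (4 adjusted over the list alone), with MVK at 1.49 ± 0.37 and a camera adjusted p of 0.0214 (adjusted p = 0.743 with an estimated correlation). Stem cell candidates fell in 5 of 10 cases and rose in 0 (5 adjusted over the list alone), with ID3 at -1.81 ± 0.28 and CEBPD at -1.32 ± 0.32. The study chose 2 members of that list on these cells, and its camera adjusted p was 0.00424 (adjusted p = 0.743 with an estimated correlation). Ribosomal protein genes passed in 0 of 20 cases by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2), RPL5 at -0.78 ± 0.42, while their camera adjusted p was 0.0292 (adjusted p = 0.743 with an estimated correlation). The median log2 fold of the ribosomal list was -0.656 in library 1 and -0.048 in library 2. Of 10 inflammatory genes 2 rose and 4 fell (7 adjusted over the list alone), CXCL1 at -2.37 ± 0.27 and IL1RN at 2.02 ± 0.23, and the list had a camera adjusted p of 0.408. Of 8 Notch genes 2 rose and 0 fell (3 adjusted over the list alone), with HES4 at 1.74 ± 0.23 and NOTCH1 at 1.26 ± 0.32, and a camera adjusted p of 0.520. Of 18 antigen presentation and interferon genes 1 rose and 4 fell (5 adjusted over the list alone), with IFITM3 at -2.42 ± 0.28, IFI6 at -1.38 ± 0.33 and a camera adjusted p of 0.145. DESeq2 called 16 mitosis, 8 DNA replication, 8 chromatin and growth, 2 tight and gap junction, 1 desmosome, 1 cornified envelope, 0 cholesterol synthesis, 2 stem cell candidate, 2 antigen presentation and interferon, 4 inflammatory and 1 Notch genes. The proliferating-like class had the deepest cells, with a median of 22904 UMIs against 7224, and the highest median doublet score of the clusters, 0.0792. KRT12, a marker of the differentiated-like class, stood at 2537 CPM in proliferating-like and 310 CPM in progenitor-like cells. Whether either bears on the rise of junction and envelope genes was not tested. Without the library as a block 111 genes rose and 10 fell, and AC093496.1, CXCL3, CXCL8, FAM107A, ID4, IFITM3, SELENOM, SERPINF1 and SLC6A6 lost their calls. By DESeq2 273 rose and 90 fell, where AC093496.1, CCNB2 and SCRG1 lost theirs, and 623 genes passed at the finer clustering resolution.

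FAM3B (ENSG00000183844), a secreted cytokine-like protein, had 757 UMIs in conjunctival-like cells against 0 in progenitor-like cells, at least 297-fold higher by a floor of 3 UMIs over both libraries. The antibacterial phospholipase gene PLA2G2A was higher by a log2 fold of 8.51 ± 0.46 (SE, n = 2 libraries), the iron-scavenger lipocalin LCN2 by 6.22 ± 0.38 and the mucosal chemokine CXCL17 by 5.96 ± 0.43. The ammonium transporter RHCG was higher by 6.40 ± 0.49. SPARCL1 was lower by -5.26 ± 0.34, the Wnt modulator DKK3 by -3.93 ± 0.40 and the neurotrophin receptor NTRK2 by -3.90 ± 0.47.

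Of 10909 genes tested by edgeR, 696 rose and 450 fell at a Benjamini-Hochberg adjusted p under 0.05, and 1145 of the 1146 moved the same way in both libraries. Again the shared direction follows largely from the test. SMIM5, FAM3D, the mucin MUC21, SPRR1B, AQP5-AS1, SPRR1A and PDE4C completed the 12 highest, and SCRG1, AC093496.1, MEG3, IFITM1, FAM107A, COL18A1, VIM and C1R were among the 12 lowest. AQP5-AS1 lies antisense to AQP5, a naming marker, and its reads cannot be told from that gene's without strand information. The adjusted p of the 24 ran from 0.000268 for PLA2G2A to 0.0197 for VIM. With a prior count of 2 PLA2G2A stood at 5.08 in library 1 and 8.04 in library 2, both below its fitted fold, and COL18A1 at -5.43 and -2.67. Of the 24 genes, 11 were also among the leading genes of a cluster of either class, FAM3B, PLA2G2A and SPARCL1 among them.

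Cornified envelope genes rose in 11 of 14 cases and fell in 0 (13 adjusted over the list alone), with SPRR1B at 6.77 ± 0.38, SPRR2A at 5.73 ± 0.33 and IVL, the involucrin gene, at 5.54 ± 0.45. The list's camera adjusted p was 1.41e-11 (adjusted p = 0.698 with an estimated correlation). SPRR1B was among the 10 leading genes of the conjunctival-like cluster 14, so this list is not independent of the clustering. Tight and gap junction genes rose in 8 of 13 cases and fell in 0 (9 adjusted over the list alone), CLDN7 at 4.13 ± 0.47 and TJP3 at 4.94 ± 0.61, with a camera adjusted p of 0.000572 (adjusted p = 0.698 with an estimated correlation). Desmosome genes rose in 5 of 11 cases and fell in 0 (8 adjusted over the list alone), DSG1 at 2.57 ± 0.30 and PKP1 at 1.20 ± 0.23, with a camera adjusted p of 0.00703 (adjusted p = 0.698 with an estimated correlation). Cholesterol synthesis genes rose in 3 of 14 cases and fell in 0 (4 adjusted over the list alone), IDI1 at 1.55 ± 0.25, with a camera adjusted p of 0.00321 (adjusted p = 0.698 with an estimated correlation). Epithelial transcription factor genes rose in 4 of 16 cases and fell in 0 (5 adjusted over the list alone), GRHL1 at 2.20 ± 0.35 and ELF3 at 1.83 ± 0.39, with a camera adjusted p of 0.0347 (adjusted p = 0.698 with an estimated correlation). Of 20 oxidative phosphorylation genes 1 rose, NDUFB2 at 1.24 ± 0.28 (1 adjusted over the list alone), while the list's camera adjusted p was 0.00871 (adjusted p = 0.698 with an estimated correlation).

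Stem cell candidates fell in 2 of 10 cases, VIM and CDH2, and rose in 0 (6 adjusted over the list alone, 2 of its members having been chosen by the study on these cells). Their camera adjusted p was 0.0203 (adjusted p = 0.698 with an estimated correlation). Basement membrane and adhesion genes fell in 4 of 16 cases and rose in 0 (6 adjusted over the list alone), the anchoring genes DST at -2.31 ± 0.28 and COL7A1 at -2.30 ± 0.32, with a camera adjusted p of 0.0513. Notch genes changed in both directions, 1 up and 2 down of 7 (6 adjusted over the list alone), with HES4 at 3.22 ± 0.28 and JAG2 at -4.05 ± 0.53, and a camera adjusted p of 0.301. Their median log2 fold was 0.74 and their mean -0.09. Inflammatory genes rose in 3 and fell in 2 of 11 cases (5 adjusted over the list alone), with IL1RN at 4.31 ± 0.57, CXCL1 at -2.92 ± 0.32 and a camera adjusted p of 0.698. Wnt genes rose in 1 and fell in 2 of 9 cases (4 adjusted over the list alone), WNT10A at -3.37 ± 0.67, with a camera adjusted p of 0.148. Antigen presentation and interferon genes rose in 3 and fell in 3 of 18 cases (7 adjusted over the list alone), MX1 at 2.12 ± 0.33 and IFITM1 at -4.26 ± 0.51, with a camera adjusted p of 0.767 in the upward direction, against a median log2 fold of -0.07. DESeq2 called 1 stem cell candidate, 2 cholesterol synthesis, 2 Wnt and 4 antigen presentation and interferon genes. This class depended most on how it was drawn: 46 genes passed with looser cell filters, where COL18A1, DKK3, NTRK2, VIM and CXCL17 lost their calls among 13 of the 24, and 253 at the coarser resolution. The looser filters kept 16701 cells against 16672, but the clusters named conjunctival-like changed. In library 2 the class held 1161 cells with the looser filters and 1164 at the coarser resolution, against 372. Without the library as a block 128 rose and 37 fell, where PLA2G2A, RHCG, NTRK2 and VIM lost their calls among 10 of the 24, and by DESeq2 393 rose and 198 fell, where FAM3B and VIM lost theirs.

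TSPAN7 (ENSG00000156298), a tetraspanin, and SOX17, a transcription factor, are the genes the study put forward as limbal stem cell markers, so they were followed through every class. SOX17 (ENSG00000164736) had a UMI in 56 of 64 vascular endothelial-like cells (87.5%, exact 95% interval 76.9 to 94.5) and in 1 of 2199 limbal progenitor-like cells (0.0455%, 0.00115 to 0.253), at median depths of 7654 and 7224 UMIs. TSPAN7 had a UMI in 54 of the 64 vascular endothelial-like cells (84.4%, 73.1 to 92.2) and in 23 of the 2199 progenitor-like cells (1.05%, 0.664 to 1.57). The summed level was 688.2 CPM for SOX17 and 342.4 CPM for TSPAN7 in vascular endothelial-like cells, against 0.115 and 1.15 CPM in progenitor-like cells.

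Of the 65 cells with a SOX17 UMI 56 were vascular endothelial-like, and these held 357 of the 366 SOX17 UMIs. SOX17 was not a naming marker, but it stood among the 10 leading genes of that cluster. For TSPAN7 the class held 47 of 112 positive cells and 161 of 229 UMIs in library 1, and 7 of 54 cells and 25 of 72 UMIs in library 2, while 36 and 18 of the positive cells were unnamed. Melanocyte-like cells showed a TSPAN7 UMI in 2.15% (0.262 to 7.55) in library 1 and 6.25% (3.16 to 10.9) in library 2, at medians of 4822 and 5610 UMIs. Proliferating-like cells showed it in 4.93% (2.01 to 9.89) and 0.546% (0.0138 to 3.01), at 25905 and 21124 UMIs, and in 0 cells when thinned to 3000 UMIs. Conjunctival-like cells showed it in 0.420% (0.115 to 1.07) at 14563 UMIs and differentiated-like cells in 0.334% (0.160 to 0.613) at 12870 UMIs. With each cell thinned to 3000 UMIs, SOX17 was seen in 70.3% and TSPAN7 in 56.3% of vascular endothelial-like cells, and TSPAN7 in 0.409% of progenitor-like and 0.100% of differentiated-like cells; 0 cells were shallower. Both genes lay below the edgeR expression filter in the proliferating-like, differentiated-like, conjunctival-like and melanocyte-like tests, and the vascular endothelial-like class had too few cells in library 2 for a test. In the same 64 cells CLDN5, the claudin of vessel walls, had a UMI in 62 and ECSCR, an endothelial surface gene, in 61. CLDN5 was a naming marker of this class, so its share was set by the naming, while ECSCR was not a naming marker. The keratin KRT14, which vessels should lack, had a UMI in 87.5% of them at 384.7 CPM, against 8495 CPM in progenitor-like cells, so a UMI alone does not mark expression for such abundant genes.

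**Figure D3:**
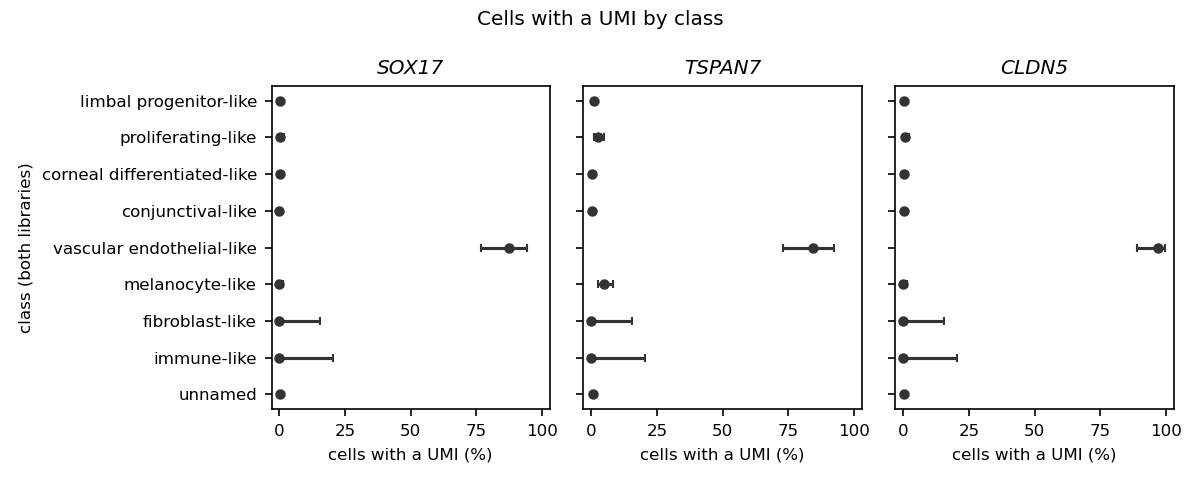
Percent of cells with at least 1 UMI of SOX17, TSPAN7 and CLDN5 in each class, both libraries together; bars are exact 95% binomial intervals. The vascular endothelial-like class stood at 87.5%, 84.4% and 96.9%, and the limbal progenitor-like class at 0.0455%, 1.05% and 0.227%. CLDN5 was a naming marker of the vascular endothelial-like class.

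Ordered from the progenitor-like class by diffusion pseudotime, epithelial cells had higher levels of cornified envelope and junction genes and lower levels of ribosomal protein genes in the last bin of both libraries. Between the first and last of 5 equal bins the mean log2(CPM + 1) of the cornified envelope list changed by 1.74 ± 0.02 (SD, n = 2 libraries), that of tight and gap junction genes by 1.73 ± 0.08 and that of desmosome genes by 0.85 ± 0.27. Cholesterol synthesis genes changed by 0.84 ± 0.01, ribosomal protein genes by -0.86 ± 0.01 and stem cell candidates by -0.68 ± 0.08. Mitosis genes went opposite ways, at 2.53 in library 1 and -0.22 in library 2, and DNA replication genes at 0.51 and -0.76, each within the spread between libraries. Ordered along the first principal component both lists were lower in the last bin of libraries 1 and 2, mitosis genes at -0.75 and -1.37 and DNA replication genes at -0.51 and -0.78. Progenitor-like cells made up 73.6% of the first bin in library 1 and 57.2% in library 2. The last bin was 71.3% differentiated-like in library 2, while in library 1 it mixed 29.01% differentiated-like with 33.1% conjunctival-like cells. It also held 116 proliferating-like cells (8.855%) in library 1 and 0 in library 2, and mitosis genes rose only in library 1. No test was made on the order, and the root was set to the progenitor-like class.

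**Figure D4:**
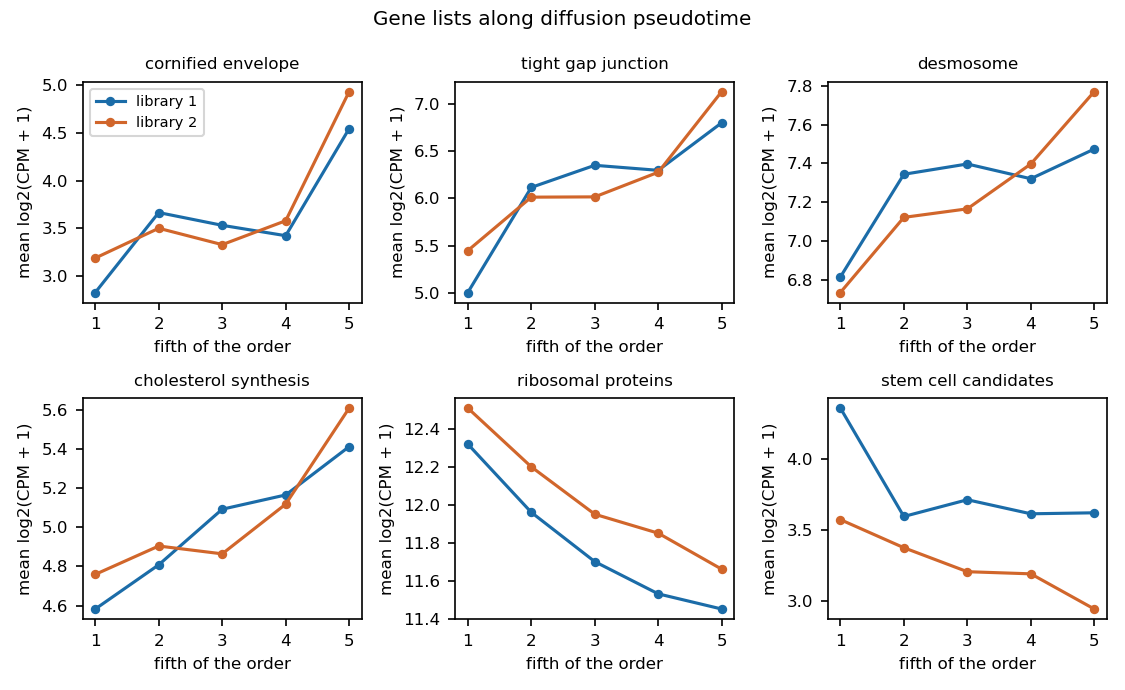
Mean log2(CPM + 1) of 6 gene lists in 5 equal bins of diffusion pseudotime, from the limbal progenitor-like root at bin 1, for library 1 and library 2. Ribosomal protein genes went from 12.3 to 11.5 in library 1 and from 12.5 to 11.7 in library 2, and cornified envelope genes from 2.83 to 4.55 and from 3.19 to 4.94.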

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

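The naming limit of 0.5, separate clustering of the libraries and naming without the leading gene condition were chosen after seeing the data. Over all alternatives the 212 named gene results gave 3165 values, of which 2721 were counted as the same. Among these, 162 values without library 1 and 173 without library 2 had no test. They were counted when they lay within the spread of the same 2 libraries around the fitted fold, which is a weak check. The rest of the 2721 kept direction and side of the threshold. Of the other values 329 kept direction but lost the threshold, 24 gained it, 89 single-library values moved beyond the spread and 2 changed sign. The sign changed for DLL1 in proliferating-like cells, at 0.29 with resolution 2.0 and 0.09 with libraries clustered separately, where it had not passed to begin with; the cause was not tested. Fits without the block weakened 115 of the 212, the looser cell filters 47, DESeq2 and resolution 0.5 38 each, libraries clustered separately 24 and resolution 2.0 22. Of genes changed in differentiated-like cells there were 636 without the replicate block, 1413 by DESeq2, 1913 with the naming limit of 0.5 and 1833 with libraries clustered separately, against 3185. In proliferating-like cells the counts were 121 without the block, 363 by DESeq2, 623 at resolution 2.0, 707 with libraries clustered separately and 538 without the leading gene condition, against 1257. In conjunctival-like cells they were 165 without the block, 591 by DESeq2, 253 at resolution 0.5 and 46 with 200 genes and 20% mitochondrial UMIs, against 1146. They were 2059 without a count filter, 1906 with all classes in a single fit, 1847 at resolution 2.0 and 1979 with doublets kept. The cause was not tested, except that the fit without a filter tested more genes by its construction. The share of differentiated-like cells was 21.71% at resolution 0.5, 11.11% at resolution 2.0, 10.2% with doublets kept, 9.436% with libraries clustered separately and 7.429% with the naming limit of 0.5 (SD 8.96). Conjunctival-like cells took 12.57% at resolution 0.5 and 10.43% with the looser cell filters, progenitor-like cells 10.01% with all UMIs, and proliferating-like cells 2.199% with doublets kept and 2.273% with all UMIs. Fibroblast-like cells took 1.25% with libraries clustered separately and 1.242% without the leading gene condition. Immune-like cells took 0.08242% with genes scaled over both libraries, 0.08227% with the looser filters, 0.08535% with doublets kept and 0.08039% with libraries clustered separately. Unnamed cells took 48.02% at resolution 0.5, 63.16% at 2.0, 63.75% with doublets kept, 63.09% with all UMIs, 65.11% with libraries clustered separately and 68.62% with the naming limit of 0.5. With each library left out the shares ranged as the libraries themselves. TSPAN7 was then seen in 82.46% to 100% and SOX17 in 85.96% to 100% of vascular endothelial-like cells. SOX17 was seen in 0.1422% of progenitor-like cells at resolution 2.0 and in 0.1474% with libraries clustered separately, where the vascular endothelial-like class had 0 cells in library 2 and 75.4% of the cells with a SOX17 UMI. Every list called by camera lost its call with an estimated correlation, at an adjusted p of 0.671 in differentiated-like, 0.743 in proliferating-like and 0.698 in conjunctival-like cells. Ordered along the first principal component, the change from first to last bin was 1.437 for cornified envelope, 1.91 for tight and gap junction, 0.887 for cholesterol synthesis, -1 for ribosomal protein, -1.061 for mitosis and -0.647 for DNA replication genes. The comparison with superficial cells was not run, since no setting named such cells, and leaving out a library left no test for a count of genes. With 7 cells in library 2, the vascular endothelial-like class was too small for a test.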

Other observations

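The tests of free RNA, and of doublets in library 2, were chosen only after the result was seen.

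In differentiated-like cells members of further lists passed by edgeR, and camera called none of these lists. Of 20 antioxidant genes 10 rose and 3 fell (14 adjusted over the list alone, 8 by DESeq2), with the quinone reductase NQO1 at a log2 fold of 2.21 ± 0.33 (SE, n = 2 libraries), thioredoxin TXN at 1.61 ± 0.30 and the mitochondrial dismutase SOD2 at -1.48 ± 0.25, and a camera adjusted p of 0.0836. Of 14 glycolysis genes 4 rose and 0 fell (4 adjusted over the list alone), with HK2 at 1.56 ± 0.30, ENO1 at 1.55 ± 0.30 and a camera adjusted p of 0.177. Of 16 basement membrane and adhesion genes 2 rose and 5 fell (7 adjusted over the list alone, 3 by DESeq2), with the hemidesmosome genes DST at -1.82 ± 0.25 and ITGB4 at -1.02 ± 0.25, the laminin receptor BCAM at -1.47 ± 0.24 and a camera adjusted p of 0.403. Of 18 DNA replication genes 1 rose and 5 fell (6 adjusted over the list alone, 0 by DESeq2), with MCM3 at -1.22 ± 0.32, LIG1 at -1.28 ± 0.36 and a camera adjusted p of 0.0836. Of 16 epithelial transcription factor genes 5 rose and 1 fell (6 adjusted over the list alone), with OVOL1 at 2.02 ± 0.30, GRHL1 at 1.85 ± 0.31, HOPX at -2.49 ± 0.26 and a camera adjusted p of 0.261. Oxidative phosphorylation genes rose in 3 of 20 cases (3 adjusted over the list alone; camera adjusted p = 0.252), mitosis genes in 1 of 3 (1 over the list alone, 0 by DESeq2; 0.334) and immediate early and stress genes rose in 3 and fell in 1 of 16 (4 over the list alone; 0.912).

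In proliferating-like cells few genes of the remaining lists passed by edgeR. Basement membrane and adhesion genes rose in 2 and fell in 1 of 16 cases (4 adjusted over the list alone, 1 by DESeq2), antioxidant genes rose in 1 and fell in 1 of 20 (2 over the list alone), glycolysis genes rose in 1 of 14 (0 over the list alone, 0 by DESeq2), Wnt genes fell in 1 of 9 (2 over the list alone, 0 by DESeq2) and epithelial transcription factor genes fell in 2 of 16 (4 over the list alone, 0 by DESeq2). Oxidative phosphorylation genes passed in 0 of 20 (0 over the list alone, 4 at an unadjusted p under 0.05, 0 by DESeq2). These 6 lists shared a camera adjusted p of 0.408. Immediate early and stress genes rose in 1 and fell in 1 of 16 (2 over the list alone, 1 by DESeq2; camera adjusted p = 0.778). In conjunctival-like cells antioxidant genes rose in 3 of 20 cases (3 over the list alone; 0.0513) and glycolysis genes in 1 of 14 (1 over the list alone, 0 by DESeq2; 0.851). By edgeR 0 genes passed of 17 DNA replication, 13 chromatin and growth, 20 ribosomal protein, 16 immediate early and 2 mitosis genes. At an unadjusted p under 0.05 these were 1, 3, 0, 5 and 1, by DESeq2 0, 0, 0, 1 and 0, and over the list alone 0, 0, 0, 0 and 1, with camera adjusted p of 0.150, 0.117, 0.201, 0.150 and 0.767. Among the unnamed clusters, cluster 5 (14.9% of library 1, 0.613% of library 2) was led by GPHA2 with KRT15 among its 10 leading genes, but its markers scored 0.05 as progenitor-like. Cluster 1 (0.774% and 24.0%) was led by INHBA, SLC7A11 and PTGS2, and cluster 6 (0.179% and 10.5%) by RSAD2, an antiviral interferon-induced gene.

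SOX17 UMIs lay mostly in vascular endothelial-like cells. Free RNA would give all classes a like share, but the lower bound of this class was 76.8% and the highest upper bound of the other classes with at least 20 cells was 15.4%. That upper bound came from 0 of 22 fibroblast-like cells. The shares counted all UMIs, those used to cluster included, and restate the pattern, so they are no separate test. In the second portion of UMIs alone SOX17 stood at 688.2 CPM in this class and 0.115 CPM in progenitor-like cells. Doublets with epithelial cells were argued against in library 1, where the median of 5 epithelial genes (KRT5, KRT14, KRT15, S100A2 and COL17A1) was 3.13% of the progenitor-like CPM over 57 cells, and stayed open in library 2, where it was 15.3% over 7 cells. Of 14 endothelial genes not used for naming, 12 were, over both libraries together, at least 5 times the progenitor-like CPM, such as CLEC14A at 296 against 0 CPM and S1PR1 at 141 against 0.115, while SOX7 and RASIP1 were not. Vascular endothelial cells in the preparation are, as a hypothesis, a candidate source of most SOX17 UMIs in library 1. In library 2 the 7 cells of the class held 36 of the 37 SOX17 UMIs. Whether those 7 cells are doublets with epithelial cells stays open, and separate clustering found no such class in library 2.

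Ribosomal protein genes were lower in differentiated-like than in progenitor-like cells, which were shallower. In cells of 8000 to 12000 UMIs the list's median log2 fold was -0.989 in library 1 and -0.743 in library 2, against -0.843 and -0.616 over all cells, which argues against depth per cell. Without the 50 most abundant other genes of either class it was -0.694 and -0.513, which argues against a few abundant genes as the whole cause. No biological explanation was tested. The list's camera call was lost with an estimated correlation (adjusted p = 0.671), a form of the test that could call almost no list here.

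Epithelial cells lay next to cells of their own library, with 92.6% own-library neighbours against 51.9% if mixed at random, and melanocyte-like cells did so at 94.6%. With each cell thinned to 3000 UMIs the share was 91.2%, which argues against depth. Without the 12 immediate early and heat shock genes among the variable genes it was 92.1%, which argues against these genes as the cause. With 1 library per donor, library preparation and donor cannot be told apart, and either could set the split of classes into clusters of a single library.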
